A study of Homo sapiens with 4 samples.

How the data were processed

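H3K79me2, a methyl mark on histone H3 placed by the enzyme DOT1L and known from the 5' part of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in OMM2.3, an established uveal melanoma cell line. The labels describe 4 samples, 2 with an antibody against H3K79me2 and 2 with IgG. A peak list was analysed for each of the 2 H3K79me2 samples, and the IgG samples were not analysed here. The labels number the samples of each kind as replicates 1 and 2 and give antibody catalogue numbers that rise by 1 between replicates in both kinds, such as ab3594 and ab3595 for H3K79me2. Whether different antibodies were used is therefore unclear. Nothing in the labels says that the replicates came from separate cultures.

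Peaks were called with MACS2 on hg38, with HOMER also named, per the submitters' processing notes. Versions, thresholds, the aligner, and whether an IgG library served as control are not given in the sources used here. The peaks were called per sample, since each H3K79me2 sample has its own deposited list. Per the layout of the deposited lists, each peak has a fold enrichment, a ratio of the fragments at the summit to a local background. The deposited lists also give −log10 of the p-value and −log10 of the q-value of each peak. The deposited score is 10 times −log10 q cut to a whole number. These are the authors' values for single peaks and were used to describe, rank or filter peaks within a list. Chromosomes 1 to 22 and X were kept.

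The number of fragments over each summit and the local background were recovered from the deposited fold and −log10 p, taking fold as (fragments + 1)/(background + 1) and p as a Poisson upper tail. All 9810 and 12216 peaks gave a whole number of fragments within 5e-05 of −log10 p, or within 2 ppm for large values. The summits held a median of 10 fragments in both lists, with 10th and 90th percentiles of 7 and 16. The lowest common background, with an assumed effective genome of 2.7e+09 bp, corresponds to about 8700000 and 9350000 fragments. Background values above that floor were whole multiples, within 0.05 of a step, of 0.0145 in replicate 1 and 0.0146 in replicate 2. A step times 20000 came to 289.1 and 292.1 bp, beside shortest peaks of 287 and 290 bp, so a step was read as 1 fragment end in a window of 10 kb. All 96 peaks of replicate 1 and all 106 of replicate 2 with more than 40 fragments had a background large enough to hold their own fragments. The background was therefore taken to come from the H3K79me2 library itself. Both readings are inferences from the values.

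Genes came from a RefSeq table of GRCh38.p14, which has the chromosome coordinates of hg38. It gives gene starts and ends without strand, so the window planned for the 5' end could not be placed. The window used was instead the 5 kb inside each of both annotated ends of a protein-coding gene, or the whole gene up to 10 kb, and the planned split by direction of transcription became a split into inside and outside the gene. Of the table, 679 genes (153 of them protein-coding) listed out of positional order were left out after a first look at the results, because they were taken to be genes of scaffolds or patches, an inference from the order of the table. There remained 19821 protein-coding genes. A gene was called marked in a replicate when a peak overlapped its window by 1 bp or more. Marked thus means only that a peak was called there, and whether the peaks carry H3K79me2 was not tested.

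Overlap of the lists was compared with 10000 circular shifts of the other list along each chromosome (one-sided), and summit positions with 10000 circular shifts (two-sided). Shifts of 0.1 to 1 Mb gave a local chance value, chosen after seeing the data. Marked genes in 21 gene lists and 11 gene families, and on each chromosome, were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. The result of a family among these is not reported here. Shares have 95% Wilson intervals and counts 95% Poisson intervals, which cover counting error only. The lists, the rule for named genes, and the tests and alternatives planned for them were fixed before the data were examined. The window at both gene ends, the local shifts, the tests of gene bodies, the alternatives without peaks of −log10 q of at least 20 and with shared base pairs, the match on gene length over gene bodies, and the tests of shared fragments came after. The rule names the 15 genes with most base pairs under peaks of both replicates, the 15 with the highest fold in their windows, the members of 4 lists on DOT1L, NAD and uveal melanoma, and from each other list up to 4 marked and 2 unmarked genes. The alternatives fixed before were stricter −log10 q, equal list lengths, reciprocal overlap of 50%, each replicate alone, other gene windows, an overlap of 500 bp, either replicate, and gene length in 10 classes.

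Whether the replicates shared fragments was tested after identical peak boundaries had been seen. Fragment ends in the 10 kb window around summits within 100 bp of each other were counted from the recovered background, leaving out those over the summit. The squared difference between the replicates was divided by its variance for independent Poisson fragments, with 2000 bootstrap samples of the windows. On simulated data, libraries with no common fragment gave a ratio of 0.992 over 46940 windows, and libraries sharing 60% gave an estimate of 60.1% over 52942. Simulated pileups were recovered in 100% of 1921 peaks, and all 200 genes planted among 19821 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.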

Results

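The series set out to map H3K79me2 across the genome of OMM2.3 uveal melanoma cells. Replicate 1 had 9810 peaks over 4392 kb and replicate 2 had 12216 peaks over 5611 kb. The peaks were narrow, with median widths of 390 and 399 bp, and weak, with a median fold enrichment of 4.32 and 4.27. Only 984 peaks (10.03%) of replicate 1 and 1176 (9.63%) of replicate 2 had a −log10 q of at least 5. There is 1 group with peak lists, so no comparison between conditions was made.

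The first question was whether the replicates marked the same places. The same strong positions led both lists, such as SERINC2, which encodes a membrane protein, with a peak of replicate 1 at chromosome 1, 31431748 to 31432187 (hg38), of fold 13.6, and one of replicate 2 that began 3 bp before it, of fold 13.9. The peaks at MS4A5, MBTD1 and PARK7 also appeared in both. Of the peaks of replicate 1, 4525 (46.1%) overlapped a peak of replicate 2, and 4518 (37.0%) of those of replicate 2 overlapped one of replicate 1. Random shifts gave means of 0.424% and 0.341% (one-sided permutation p = 0.0001 for both, the smallest that 10000 shifts can give). Across the 4525 peaks, fold enrichment had a Spearman's rho of 0.620 and a Pearson's r of 0.751 on the log2 scale. Peaks are not independent replicates, and no p-value was computed.

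The replicates could not be treated as independent. The peak in PRKCA, a protein kinase C gene, ran from 66806748 to 66807171 on chromosome 17 in both lists, to the base pair, over 11 and 12 fragments. The peak between OSGEP and APEX1 on chromosome 14 began at 20454808 in both. Among 4534 overlapping pairs, 785 (17.3%) had the identical start, against a mean of 23.1 pairs at each offset of 1 to 10 bp, and 749 had the identical end. Among the 1180 pairs with −log10 q below 3 in both, 251 (21.3%) had the identical start. In 1428 windows of 10 kb around shared summits, with medians of 58 and 63 fragments, the replicates differed by 0.417 of the variance expected of independent libraries (95% interval 0.388 to 0.445). These windows were chosen because both lists had a summit there and a background well above the floor. Within them, fragment counts thus differed by less than the sampling noise. The lists were therefore counted as 1 sample. Values are given for both lists, and neither the overlap nor the p-values measure variation between cultures.

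**Figure D1:**
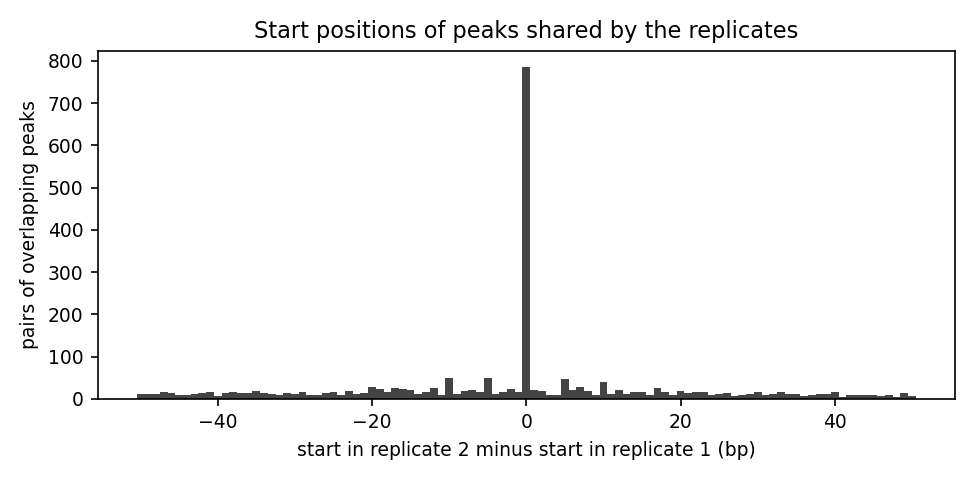
Number of overlapping peak pairs (vertical axis) by the start in replicate 2 minus the start in replicate 1 (horizontal axis, bp, from −50 to 50). The bar at 0 holds 785 pairs, and the mean at offsets of 1 to 10 bp is 23.1.

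The second question was where peaks lay relative to genes. Summits gathered at the very ends of protein-coding genes and were sparse inside them. The summits at TTC31, PARK7 and RBX1, which encodes a ubiquitin ligase subunit, lay 0.066, 0.038 and 0.213 kb from a gene end in replicate 1. In all, 515 summits of replicate 1 lay within 1 kb of a gene end, 1.92 times the local chance value (95% interval 1.76 to 2.09), and 622 of replicate 2, 1.89 times (1.74 to 2.04). The excess was present on both sides, 2.02 and 1.99 times outside the gene and 1.82 and 1.79 times inside it. From 1 to 5 kb inside genes, summits stood at 0.676 and 0.678 of local chance (0.601 to 0.757 and 0.610 to 0.751). These local values rest on 200 shifts and were chosen after seeing the data, with a two-sided permutation p of 0.010 for each, the smallest they can give.

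**Figure D2:**
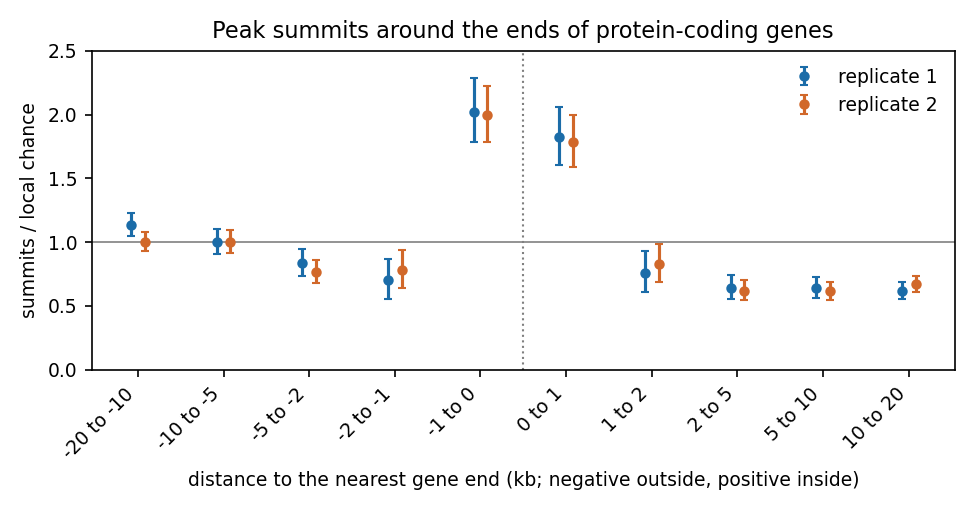
Ratio of summits to local chance (vertical axis) by distance to the nearest end of a protein-coding gene (horizontal axis, kb, negative outside the gene). Points are the 2 replicates with 95% Poisson intervals; only the classes within 1 kb of the end lie near 1.8 to 2.0.

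The window of the main test, 5 kb inside both gene ends in place of the planned 5' window, held 5.94% of summits in replicate 1 (95% Wilson interval 5.49 to 6.43) and 5.72% in replicate 2 (5.32 to 6.15). Chance gave 5.62% and 5.57%, and the difference did not pass the test (two-sided permutation p = 0.25 and 0.55). With local shifts, also chosen after seeing the data, the shares were 0.96 and 0.93 of chance (two-sided permutation p = 0.34 and 0.032). With shifts along the whole chromosome and −log10 q of at least 5 they were 0.743 and 0.903 of chance, which did not pass the test (two-sided permutation p = 0.086 and 0.51). Whole gene bodies, a feature chosen after seeing the data, held 33.0% and 33.6% of summits against 42.2% and 42.1% by chance (two-sided permutation p = 0.0002 for both, the smallest possible). This share was 35.1% and 36.5% for peaks with −log10 q below 2 and 9.30% and 10.3% for those of 20 or more. The last class held only 86 and 87 peaks, and no chance value was computed for it alone. Its 20 strongest peaks held 83 to 1175 fragments in replicate 1 and 85 to 1200 in replicate 2, against a median of 10 over all peaks. Whether they carry the mark was not tested, so the fall does not show that strong marking avoids genes.

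**Figure D3:**
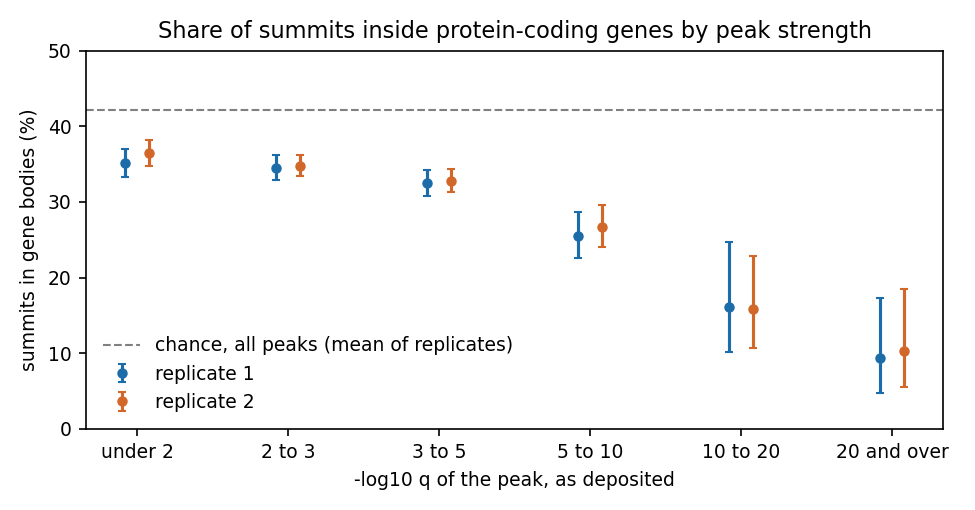
Share of summits in protein-coding gene bodies (vertical axis, %) by the deposited −log10 q of the peak (horizontal axis, classes), for the 2 replicates with 95% Wilson intervals. The dashed line is the chance share of all peaks, and the share falls from 35.1% and 36.5% in the weakest class to 9.30% and 10.3% in the strongest. The strongest class holds 86 and 87 peaks, for which no separate chance share was computed.

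The third question was which genes were marked. In both lists 321 of 19821 protein-coding genes (1.62%) had a peak in their end windows, from 677 in replicate 1 and 841 in replicate 2. The highest folds were at SERINC2, MS4A5, the deubiquitinase copy USP17L22, MBTD1, TTC31 and TBC1D3H, followed by PARK7, a gene of oxidative stress defence, and APEX1, the DNA repair endonuclease. Several of these peaks lay between neighbours and counted for both, as with OSGEP and APEX1 (fold 6.18 and 8.36), CAGE1 and RIOK1 (5.82 and 8.10), and LONP1, the mitochondrial protease, and CATSPERD (6.53 and 6.49). RBX1 (5.79 and 8.03) and ELF5 (7.40 and 5.72) completed the 15. USP17L22 and TBC1D3H belong to families of near-identical copies, so their peaks are uncertain. The peak at SERINC2 held 274 and 293 fragments, against a median of 10 over all peaks of either list. Whether that peak carries the mark was not tested. The peaks of the replicates shared base pairs inside the windows of 304 genes, and 100 shifts of the shared intervals gave 276.7 ± 17.4 (SD over shifts, range 229 to 319). The count of 304 thus lay within the range of the shifts. At −log10 q of at least 5, 32 genes were marked in both lists. SERINC2, with its summit 2.83 kb from a gene end in replicate 1, and ELF5 were not marked with a window of 2 kb around the ends.

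The genes with most base pairs under peaks of both replicates were mostly very long. AGBL4 on chromosome 1 (1501 kb) had 4263 bp, CPQ on chromosome 8 (498.3 kb) 3072 bp and EYS on chromosome 6 (1987 kb) 2995 bp. SNTG1, CCSER1, STXBP5L, GALNT13, ENTHD1, ZBTB7C, MAGI2, KIF6, EPHA6 and COL21A1 followed with 2598 to 1934 bp. The predicted genes LOC124903442 (4322 bp) and LOC107985915 (3195 bp) were the short exceptions. Their peaks held 68 to 108 and 43 to 78 fragments, against a median of 10 over all peaks of either list. Whether these peaks carry the mark was not tested. In AGBL4 these were scattered narrow peaks, such as 49551571 to 49552150 (fold 7.08 in replicate 1). The longest peak anywhere was 3125 bp in replicate 1 and 3354 bp in replicate 2. Such lists cannot show whether a broad domain was present. Over all genes, 1116 bodies held base pairs shared by both lists, fewer than the 1427 ± 33.9 of 100 shifts (SD over shifts, range 1333 to 1511).

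Gene lists showed no enrichment. Of 453 list genes, 8 were marked in both lists, and 0 of 32 lists and families passed an adjusted p of 0.05 by Fisher's exact test (lowest adjusted p = 0.41). At −log10 q of at least 5, none of these 8 genes was still marked. An unadjusted p below 0.05 was reached by 2 of the 32 lists and families. The tricarboxylic acid cycle had 2 of 22 members marked, SUCLG2, a succinyl-CoA ligase subunit (fold 5.08 and 5.39), and DLD, a dehydrogenase subunit (5.12 and 6.12), with Fisher's exact p = 0.049 and adjusted p = 0.78. Olfactory receptors had 13 of 389 marked (3.34%, Fisher's exact p = 0.013, adjusted p = 0.41), among them OR6N1, OR10J1, OR2V2 and OR12D2. Some of the 13 are neighbours on chromosome 1, so they are not independent. In simulations a list of 20 genes marked at 10 times the average rate was called in 45% of 200 runs and one of 40 genes in 82%. At 5 times the average rate these fell to 4% and 22%, so a moderate enrichment of a small list would mostly have been missed.

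Genes of the DOT1L complex and transcription elongation had 0 of 25 members marked, DOT1L among them, and NAD biosynthesis had 0 of 19, with neither NAPRT nor NAMPT marked. With 1.62% of all genes marked, 0 is an ordinary count for these and the other lists of such size. It does not show that their members lack the mark. Of the uveal melanoma drivers 0 of 9 were marked, including GNAQ, GNA11, BAP1 and SF3B1, and of the melanocyte and pigmentation genes 0 of 28, ABCB5 and BCL2A1 among those with no peak in either list. The expression classifier of uveal melanoma had 0 of 13 marked in both lists, and PRAME had a peak of fold 3.50 in replicate 2 alone. Inside gene bodies, away from the ends, both lists shared peaks in NMNAT3 of the NAD biosynthesis list (fold 6.38 and 4.69 at the stronger), PLCB4 (4.67 and 5.49) and MTUS1 (4.41 and 3.99). They also shared peaks in MLLT1 of the DOT1L list (4.03 and 4.12) and, of the melanocyte list, KIT (6.41 and 6.21) and TRPM1 (4.79 and 5.37), which were chosen after their values were seen. The cell cycle list had 2 of 43 marked, CDK4 (4.73 and 4.97) and CDC45 (6.95 and 5.69).

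The Gq, PKC and MAPK list had 1 of 33 marked (PRKCA), apoptosis and autophagy 1 of 32 (BID), retinal pigment epithelium 1 of 10 (BEST1, fold 5.25 and 4.20) and T and B lymphocytes 1 of 20 (IL7R). The HOXA cluster with MEIS1, DNA repair, glycolysis and pentose phosphate, histone methylation enzymes, photoreceptor, hepatocyte, monocyte and macrophage, endothelial, fibroblast and pericyte, and neuronal lists had 0 marked. Among families, ZNF genes had 5 of 509 marked, mitochondrial ribosomal proteins 2 of 77 (MRPL11 and MRPL54), and ribosomal proteins 1 of 85 (RPL7). Complex I subunits had 1 of 36 (NDUFB4) and keratin-associated proteins 1 of 94 (KRTAP16-1). Proteasome subunits, translation initiation factors, histone genes and DEAD-box helicases had 0. With whole gene bodies 16 of 509 ZNF genes were marked, against 1450 of all 19821 genes (7.32%; Fisher's exact test, adjusted p = 0.0021). Genes marked over bodies were long (median 140.4 kb, 24.5 kb for all genes), and with genes matched on length, an alternative chosen after seeing the data, the ZNF difference did not pass an adjusted Mantel-Haenszel test (odds ratio 0.582).

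The last question was whether chromosomes differed. By Fisher's exact test, marked genes were more frequent on chromosome 1 (66 of 2049 genes, 3.22%, adjusted p = 1.1e-06), chromosome 6 (37 of 1042, 3.55%, adjusted p = 5.3e-05) and chromosome 20 (25 of 537, 4.66%, adjusted p = 2.9e-05). They were less frequent by the same exact test on chromosome 9 (3 of 775, adjusted p = 0.0080), chromosome 10 (2 of 733, 0.0040), chromosome 12 (7 of 1023, 0.035) and chromosome 16 (2 of 845, 0.0012). Within chromosome 6 the peaks crowded into the first 70 Mb, with 8.37 and 10.1 peaks per Mb, against 0.725 and 0.864 per Mb beyond. On chromosome 8 the first 45 Mb had 1.73 and 2.44 per Mb and the rest 5.59 and 6.91. On chromosome 22 the stretch from 15 to 25 Mb had 200 and 210 peaks. These stretches were chosen after seeing the counts. Neighbouring genes share peaks, so the p-values by chromosome take dependent genes as independent, and 0 chromosomes passed at −log10 q of at least 5.

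**Figure D4:**
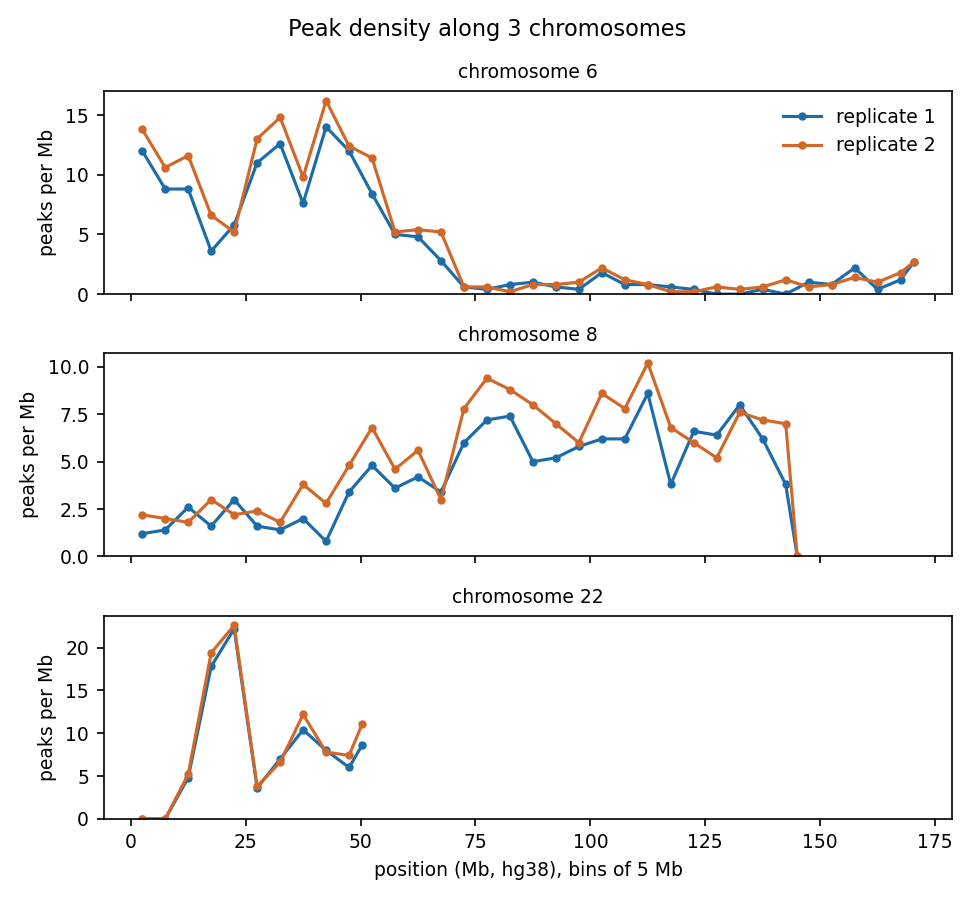
Peaks per Mb (vertical axis) in bins of 5 Mb (the last bin of each chromosome is shorter) along chromosomes 6, 8 and 22 (horizontal axis, Mb, hg38), for the 2 replicates. The first 70 Mb of chromosome 6 have 8.37 and 10.1 peaks per Mb and the rest 0.725 and 0.864.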

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

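Overlap between the lists stayed above chance under all 5 alternatives, at 39.98% to 82.7% in replicate 1 and 32.1% to 67.3% in replicate 2, and the gene body share stayed below chance, at 0.318 to 0.787 and 0.334 to 0.802 of it. Alternatives without peaks of −log10 q of at least 20, with local shifts or shared base pairs, with bodies matched on length, and all those on summits in gene bodies were chosen after seeing the data. The correlation of folds rose to 0.839 and 0.949 at −log10 q of at least 5 and 10, among fewer peaks. The 86 and 87 peaks with −log10 q of 20 or more remained at both thresholds. The ratio to chance at gene ends, not past the test with 5 kb inside both ends, was below 1 without passing the test at those thresholds (0.743 and 0.447 in replicate 1, 0.903 and 0.501 in replicate 2), and below 1 with local shifts (0.960 and 0.927) and over whole bodies (0.782 and 0.797), and passed the test for 2 kb around the ends (1.51 and 1.52). Genes marked in both lists numbered 32 and 3 at the stricter thresholds, 39 with 500 bp of overlap, 1450 over bodies, 1197 in either list, and 677 to 841 without one replicate. Of 23 named marked genes, 15 and 2 were still marked at the stricter thresholds, 17 with 2 kb around the ends (without SERINC2, ELF5, PRKCA, SUCLG2, BID and IL7R) and 0 with 500 bp. Lists passing were 1 over bodies (ZNF genes, lower), 0 over bodies with genes matched on length, and 0 otherwise. The 7 chromosomes became 0 at both thresholds and with 500 bp, 12 for 2 kb around the ends and in either list, 18 over bodies and 8 to 12 without one replicate; chromosome 16 no longer passed without replicate 2 (Fisher's exact test, adjusted p = 0.050), nor chromosome 12 with equal list lengths (0.071). The log2 odds of 1.81, 1.89, 1.39 and 1.68 on chromosomes 9, 10, 12 and 16 at −log10 q of at least 10 have the opposite sign only because 0.5 was added to counts with 0 marked genes, and are no reversals. On chromosome 20 it was −0.86 at 5, with 0 marked genes (Fisher's exact test, adjusted p = 1). The cause of the other changes was not tested. No paired analysis was possible because the IgG samples were not analysed here, and with a median of 10 fragments at a summit weaker marking may have gone uncalled, which was not tested.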

Other observations

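The strongest peaks lay mostly away from protein-coding genes. Of the 20 strongest of each list, all 20 overlapped a peak of the other list and 2 lay in a protein-coding gene, at SERINC2 and DUX4. These peaks held 83 to 1175 fragments in replicate 1 and 85 to 1200 in replicate 2, against a median of 10 over all peaks of either list. Whether such counts reflect the mark or reads piled up without it was not tested. The strongest, at chromosome 3, 93470361 to 93470793, held 1175 and 1200 fragments, 373.2 kb from the nearest annotated gene. Bodies of pseudogenes held 2.82% and 2.46% of summits, 1.76 and 1.55 times chance, and bodies of lncRNA genes 18.1% and 18.0%, 1.21 and 1.19 times chance (two-sided permutation p = 0.0002 for each, the smallest possible). With local shifts the ratios were lower, 1.55 and 1.42 for pseudogenes and 1.14 and 1.14 for lncRNA genes (two-sided permutation p = 0.0020 for each). These features were chosen after seeing the data, and the IgG samples were not analysed here.

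Of the tests that follow, those of gene-body background, of common fragments and of mappable positions were written before their results were seen, and the others after; the window setting of the test of common fragments was chosen after its values under all settings had been seen. No biological explanation was tested, since the design has 1 group with peak lists.

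Peak boundaries were identical to the base pair in both replicates far more often than at neighbouring offsets. Limits on which positions can be mapped were assumed to be rarer near genes. The identical share within 1 kb of gene ends (51 of 266 pairs) was 1.11 times that elsewhere (95% interval 0.864 to 1.44). No map of mappable positions was used, so this cannot decide whether such limits fixed the boundaries. Sequenced fragments present in both libraries, such as one library sequenced again or read sets that overlap, are the candidate explanation that the values need, since the variance ratio of 0.417 lies below 1, the value for independent libraries without other spread. The other window settings gave 0.388 to 0.429. With each fragment end counted as independent the ratio of 0.417 would be 0.834. At 0.417 about 60.5% of the fragments of replicate 1 and 56.3% of those of replicate 2 in the 1428 windows would be common. How they came to be so stays open, and fragments outside these windows were not tested.

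Summits were sparse in genes except at their very ends. Dilution by weak peaks would leave stronger peaks more often in genes, if the stronger ones carry the gene signal. Their share in gene bodies with −log10 q of at least 5 was at most 24.2%, against 34.0% and 34.6% of weaker peaks. With −log10 q of 5 to 10, leaving out the strongest, the share was 25.5% and 26.7%. Whether the stronger peaks carry the mark was not tested, so dilution is not excluded. Regional differences in density are argued against by a local ratio of at most 0.774. A signal spread over the first kilobases of genes stays open, since the ratio of at most 0.678 from 1 to 5 kb inside is part of the pattern and pools 5' and 3' ends, and a rise at 5' ends alone is not excluded. Broad domains in genes may have raised the background and hidden peaks, but the background of peaks in gene bodies was 1.024 and 1.017 times that outside (95% intervals 0.979 to 1.053 and 0.988 to 1.045), that within 5 kb of gene ends was 0.942 and 0.915 times (0.888 to 0.995 and 0.867 to 0.982), and only called peaks have a recovered value, so this stays open.

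Peak density changed in steps along chromosomes 6 and 8, and also elsewhere, as on chromosome 11 (4.87 and 6.20 peaks per Mb from 55 to 85 Mb, 0.844 and 1.09 beyond 90 Mb) and chromosome 2 (6.58 and 7.94 in the first 80 Mb, 3.04 and 3.93 beyond). Gene density explains little of it over the genome, with a Spearman's rho of at most 0.168 across 573 bins of 5 Mb. At these steps, genes per Mb fell with the peaks on chromosome 6 (8.79 and 4.24) and chromosome 11 (16.9 and 7.02). They were nearly equal on chromosome 2 (5.25 and 5.14) and went the other way on chromosome 8 (6.31 and 4.22). Regional read depth goes with it, with a rho of at least 0.591 against the recovered background in bins of 5 or more peaks. That background has a floor, is recovered only at called peaks and was taken to hold their own fragments. It is therefore not a measure of depth independent of the peaks. A hypothesis is that copy number sets this depth. Gain of the short arm of chromosome 6 and the long arm of chromosome 8 is known in uveal melanoma. The steps on chromosomes 2 and 11 have no such background here. The step on chromosome 6 was placed at 70 Mb from the counts. Whether this or any other step falls at the boundary between the arms was not examined. The hypothesis may be looked at in an input library, not analysed here.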
